A study of Arabidopsis thaliana with 2 samples.

How the data were processed

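Transcripts of LAP2-1 mutant and wild-type Arabidopsis plants were measured on 2 arrays of 2 colours, each holding both genotypes, with dyes exchanged between replicates. Per the labels, RNA was extracted from pools of 20 plants with an RNeasy kit and labelled after linear amplification. Both arrays lay on the same slide and were scanned together, per the file headers, so slide and scan could not act as batches between them. The design text speaks of replicates that were each dye-swapped; whether the arrays here come from separate pools is not given in the sources used here.

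The deposited files hold scanner output of an Agilent Arabidopsis array with 45220 spots, of which 43803 are gene spots with 43603 different probes and 1417 are controls. Per the submitters' processing notes and the file headers, Agilent Feature Extraction 9.5.3.1 made them. Per the file headers, the intensity of each spot is deposited as a mean signal and a median local background per channel, before correction. The processed signals are deposited as intensity values after background subtraction, detrending and dye normalization, and the authors' log10 ratio of red over green is derived from them. On the arrays, 18.3% and 19.3% of gene spots have a log10 ratio of exactly 0, per the deposited files. A few lines (5 and 1 in the respective files) end in a lone carriage return, which was read as a line end.

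Mean signals were corrected with normexp (offset 50) on all spots, turned to log2 ratios and normalized within each array by loess, with control spots at weight 0, in limma 3.58.1 under R 4.3.3. Files were read with the data.table package (version 1.17.8) and jsonlite 2.0.0, and plots were drawn with matplotlib 3.10.9. Spots marked as outliers (125 and 36) were left out, and saturated spots (1 in Cy5 in replicate 2, 0 elsewhere) were kept. Ratios were turned to mutant over wild type, and spots of a probe were averaged. A probe was kept where at least 1 genotype was well above background on both arrays, which left 29933 probes. The brightest probe stood for a locus, and probes without a locus stayed on their own, which gave 22378 features. Of 5846 loci with at least 2 such probes, 11 had probes over 1 log2 apart, and 34 of 956 called loci had a probe of the opposite sign. Names were taken from the reference table (assembly TAIR10.1), which held 19871 of the 20067 loci tested and gave 8643 of them a symbol. It gives AT4G30910 no symbol, and LAP3 is the name on the fixed lists. Other names from the lists stand for these symbols of the table: KN (SYP111), MAH1 (CYP96A15), LAC4 (IRX12), SDI1 (ATSDI1), CBF3 (DREB1A), MGD3 (MGDC), ICS1 (EDS16), CAO (CH1), LHCB1.1 (CAB2), RD29A (LTI78), EM6 (GEA6), BGLU23 (PYK10) and MAM3 (IMS2). Probe positions are those of the files (build ath1:Jan2004).

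The test was limma's lmFit with a single coefficient, mutant minus wild type, and eBayes, two-sided, with Benjamini-Hochberg adjustment over all features. The fit has 1 residual degree of freedom per gene and takes a prior with 12.6 degrees of freedom and an SD of 0.129, so a gene's SE rests mostly on the spread of other genes. A dye term would leave no residual, and the exchange of dyes cancels the dye effect in the mean. Errors are limma's moderated SE over n = 2 arrays unless an SD is named. The arrays' median signal over background was 5.38 to 7.61 per channel, and the number of arrays limits the precision.

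Genes were named by a rule set before the data were examined: LAP2, LAP1 and LAP3; the 12 highest and 12 lowest values among called genes with a locus and the same direction on both arrays; up to 4 members of each reported list with the largest change, those past the test first; and genes needed for a check. APR1, SEP1, the members of later lists and the probe without a locus were named after their values had been seen. Near-identical neighbours were to be merged, which was not done because transcript sequences were not used here. For a gene not well above background in a genotype on either array, and for GRP19, RNS1 and EM6, which were so on 1 array with a signal under the floor, a lower bound of the fold is given, from log2 signals per channel after loess and Aquantile. The dim side takes on each array the higher of its own signal and the lowest signal among probes well above background.

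There were 40 gene lists, of which 38 had at least 5 measured genes and were tested with camera (preset correlation 0.01, Benjamini-Hochberg over lists). They cover aminopeptidases, senescence, pigments and photosynthesis, hormones, stress, nutrients, growth, organelles and organ markers. Camera was repeated with an estimated correlation, by ranks, and against 10000 random lists matched on brightness. Other alternatives were no background correction, a normexp offset of 16, Agilent's own log ratios, median centring, Aquantile between arrays, no filter and a stricter filter on dim probes, the mean over probes, eBayes with a trend or robust, a 2-fold minimum and each array alone. Leaving out features brighter than log2 16 was added after the data had been seen.

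The procedure was tested on simulated scanner signals for the same spots, with a dye curve and known changes among 22378 genes. It recovered 38 of 67 genes changed by 0.5 (log2), 67 of 67 changed by 1 and 66 of 66 changed by 2. Of 200 genes called in all, 15 were unchanged. The median estimates were 0.42, 0.91 and 1.87, so sizes were slightly compressed. A simulated list of 15 genes shifted by 0.5 had an adjusted p of 6.47e-37 with the preset correlation and 0.989 with an estimated one. Of 50 unshifted lists, 0 were called by either. Noise was drawn independently for each gene, so this count does not tell how often lists of correlated genes are called without a shift.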

Results

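The series compared Arabidopsis thaliana plants carrying the LAP2-1 mutation with wild-type plants of the same ecotype, Columbia. LAP2 encodes leucine aminopeptidase 2, a peptidase that removes residues from the N terminus of peptides, and the study concerned its part in growth, leaf lifespan and responses to stress. Transcripts of both genotypes were hybridised together on each of 2 arrays, with the mutant in Cy5 and the wild type in Cy3 in replicate 1 and the dyes exchanged in replicate 2. Each replicate pooled 20 plants grown in soil or on medium under a 16 h photoperiod at 22 °C, while the organ and the age of the plants are not given in the sources used here. The labels do not tell whether the arrays hold separate pools or the same extracts labelled both ways. The p-values of single genes thus measure only the spread between these 2 arrays, which may be technical. Those of gene lists, given below, rest on the spread between genes and do not measure variation between plants. The root-mean-square SD between arrays was 0.149 over features. Between repeated spots within an array it was 0.143 in replicate 1 and 0.180 in replicate 2, over the 50 probes spotted more than once. The spread between arrays was thus not clearly larger than that between spots, so a spread between plants cannot be read from it. Of 43803 gene spots, 31822 (Cy5) and 30263 (Cy3) were well above background in replicate 1, and 33179 (Cy5) and 29185 (Cy3) in replicate 2. The median signal was 6.73 (Cy5) and 5.38 (Cy3) times the median background in replicate 1 and 7.61 (Cy5) and 5.52 (Cy3) times in replicate 2. The number of arrays limits the precision of every value.

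LAP2 (AT4G30920) transcript was strongly reduced in the plants labelled as mutant. It was 29.1-fold lower (log2 mutant over wild type -4.86 ± 0.0980, limma's moderated SE, n = 2 arrays; limma adjusted p = 2.05e-12), with -5.03 in replicate 1 and -4.70 in replicate 2. That value comes from the brighter of its 2 probes, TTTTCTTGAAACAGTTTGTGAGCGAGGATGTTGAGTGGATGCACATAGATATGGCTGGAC, placed by the files on chromosome 4 from 15046681 to 15046834 (build ath1:Jan2004), a span of 154 bases for a probe of 60. The other probe, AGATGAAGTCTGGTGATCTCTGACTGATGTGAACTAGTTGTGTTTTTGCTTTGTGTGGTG, lies on chromosome 4 from 15046536 to 15046595 and was 59.1-fold lower (log2 -5.88, SD 0.197, n = 2 arrays). Both probes stayed well above background in the mutant on both arrays. The brighter probe resembles a probe of LAP1 in sequence, so signal from LAP1 cannot be excluded there. The labels do not give the position of the lesion, so it is not known whether the probes lie inside it. LAP1 (AT2G24200), a close relative, had a log2 value of 0.12 ± 0.0910 that did not pass the test (adjusted p = 0.447). LAP3 (AT4G30910), the neighbouring locus, fell 1.36-fold (log2 -0.44 ± 0.0922, adjusted p = 0.00402), a call that was lost with Agilent's own log ratios (adjusted p = 0.0625) and with median centring in place of loess (adjusted p = 1.00; range over alternatives 3.81e-05 to 1.00).

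Beyond LAP2, 15 of 15 measured genes of glucosinolate synthesis, the pathway of sulfur-containing defence compounds of this plant family, were higher in the mutant. Lower were 15 of 16 genes of flavonoid synthesis, 8 of 13 of chlorophyll synthesis and 9 of 10 of the phosphate starvation response. These 4 lists passed as groups with a preset correlation between genes and did not pass with an estimated one (adjusted p = 0.582 for each). The estimated correlation also missed a simulated list with a true shift, so it cannot decide here. Whether a different time of harvest or clock phase, raised below for clock genes, contributed to these changes was not tested. Of 22378 features tested (20067 loci and 2311 probes without a locus), 1457 were higher and 2382 lower in the mutant (limma, Benjamini-Hochberg adjusted p under 0.05), which corresponds to 1327 and 2194 loci. The median size of a called change was 0.43 on the log2 scale. Changes of at least 2-fold on both arrays numbered 66 upward and 169 downward, against 1 feature that was at least 2-fold different in opposite directions. The arrays' log ratios, turned to mutant over wild type, correlated across genes with a Pearson r of 0.775 and a Spearman rho of 0.564, although genes are not independent replicates. The same limma fit made for the dye called 0 features, with 46 at an unadjusted p under 0.05, and the genotype difference inflates the residual of that fit. Of 127 named genes other than LAP2 that were called, 85 lost the call with median centring. The count of changed features fell to 131 with median centring in place of loess, where the arrays no longer correlated (r = -0.00839), to 2304 with Agilent's own log ratios and to 2454 without the filter on dim probes.

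**Figure D1:**
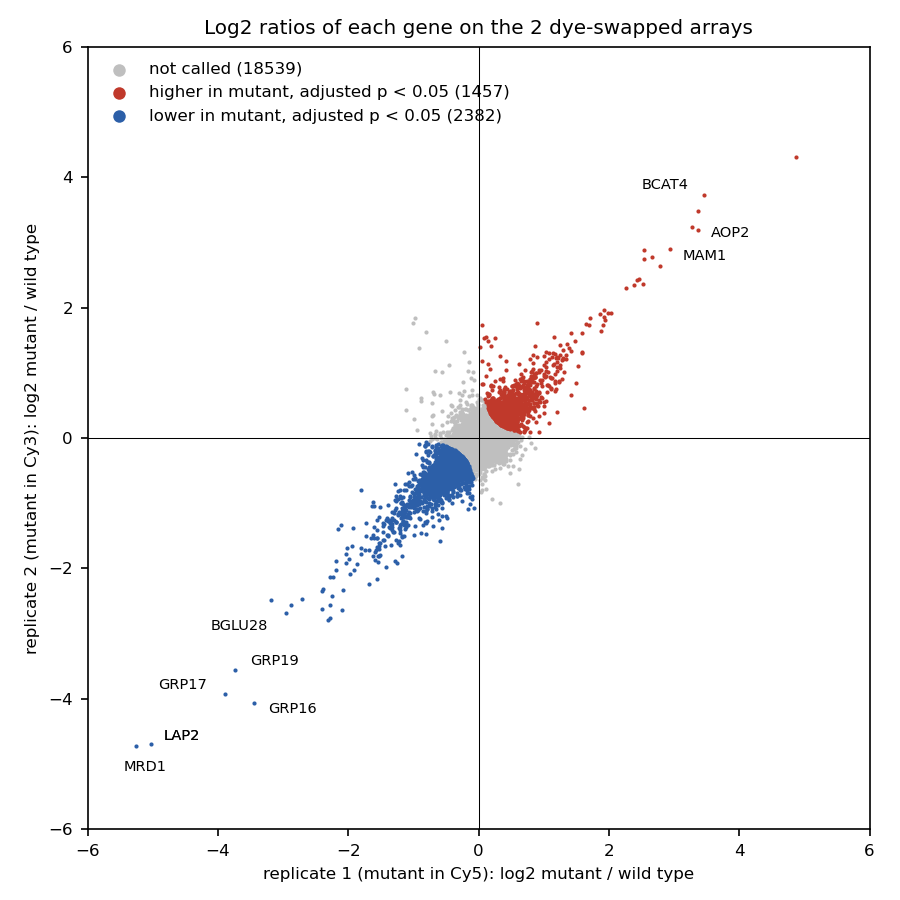
Log2 ratio of mutant over wild type for each of 22378 features in replicate 1 (horizontal) and replicate 2 (vertical), with features called higher (1457) in red, called lower (2382) in blue and the others in grey. LAP2 and MRD1 sit at the lower left with values between -4.70 and -5.26 on both arrays, and BCAT4, AOP2 and MAM1 sit at the upper right.

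The 12 genes with the highest values rose between 5.38-fold and 12.1-fold, and 3 of them belong to the glucosinolate list fixed in advance. BCAT4 (AT3G19710), an aminotransferase that opens the chain elongation of methionine for glucosinolates, rose 12.1-fold (log2 3.59 ± 0.0942, adjusted p = 1.03e-11). CYP79F1 (AT1G16410), the cytochrome P450 that turns elongated methionine into aldoximes, rose 9.56-fold (log2 3.26 ± 0.0877), and MAM1 (AT5G23010), a methylthioalkylmalate synthase of the elongation cycle, rose 7.55-fold (log2 2.92 ± 0.0877). AOP2 (AT4G03060), a dioxygenase that modifies glucosinolate side chains, rose 9.68-fold (log2 3.28 ± 0.0909), and its 2 probes gave 3.28 and 3.25. IPMI1 (AT3G58990) and IPMI2 (AT2G43100), isopropylmalate isomerases, rose 6.56-fold and 5.38-fold. FMO GS-OX1 (AT1G65860), a glucosinolate S-oxygenase, rose 5.46-fold, and the glutathione S-transferases GSTF11 (AT3G03190) and GSTU20 (AT1G78370) rose 6.60-fold and 5.44-fold. The remaining risen genes were AT5G35935, annotated in the files as a transposable element gene (10.8-fold), AK3 (AT3G02020), an aspartate kinase (6.55-fold), and PER64 (AT5G42180), a peroxidase (6.24-fold). PER64 was well above background in the wild type on 1 of the 2 arrays.

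LAP2 was among the 12 genes with the lowest values. MRD1 (AT1G53480) fell 31.8-fold (log2 -4.99 ± 0.113, adjusted p = 3.40e-12). GRP17 (AT5G07530), GRP16 (AT5G07540) and GRP19 (AT5G07550), glycine-rich oleosins of the pollen coat encoded side by side, also fell. GRP17 and GRP16 had log2 values of -3.91 ± 0.0877 and -3.75 ± 0.121, and GRP19 was at least 10.3-fold lower (adjusted p = 8.32e-12). These 3 genes are alike, and signal shared between them cannot be excluded. PGA4 (AT1G02790), a polygalacturonase, fell 6.60-fold. MRD1, the 3 GRP genes and PGA4 were well above background in the mutant on 1 of the 2 arrays. LTP12 (AT3G51590), a lipid transfer protein, and AT3G07850, an exopolygalacturonase, were not well above background in the mutant on either array and were at least 5.68-fold (adjusted p = 2.74e-10) and at least 5.80-fold (adjusted p = 3.01e-09) lower. The bounds compare the wild-type mean with the higher of the detection floor and the mutant signal on each array. BGLU28 (AT2G44460), a beta-glucosidase, fell 7.06-fold, BAM5 (AT4G15210), a beta-amylase, 5.87-fold, NUDT24 (AT5G19470), a Nudix hydrolase, 5.74-fold and CDEF1 (AT4G30140), a cutinase, 5.69-fold.

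**Figure D2:**
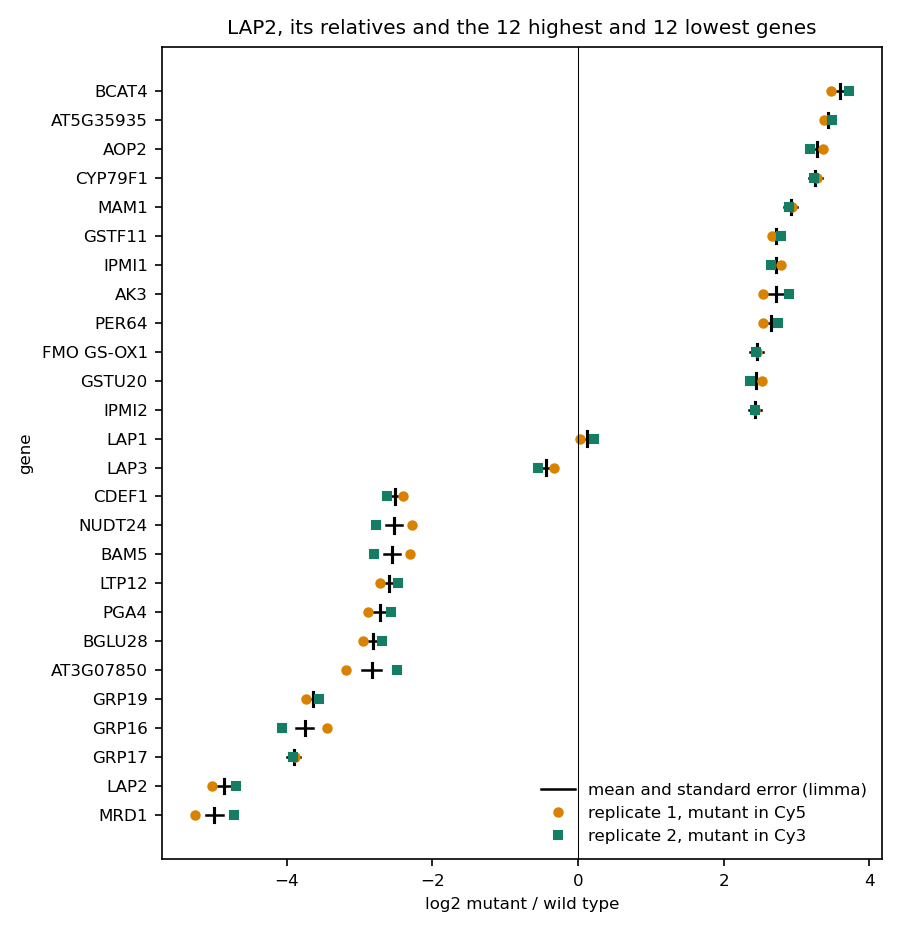
Log2 ratio of mutant over wild type (horizontal) of LAP2, LAP1, LAP3 and the 12 highest and 12 lowest called genes (vertical), with circles for replicate 1, squares for replicate 2 and black crosses for the mean and its standard error. The 12 highest genes lie between 2.43 and 3.59 and the lowest between -2.51 and -4.99, while LAP1 and LAP3 lie near 0.

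Gene lists fixed before the data were examined were tested as groups. Of 38 lists with at least 5 measured genes, 19 shifted against the other genes (camera, preset inter-gene correlation 0.01, adjusted p under 0.05), 5 upward and 14 downward. The p-values of lists rest on the spread between genes and do not measure variation between plants, however small they are. Correlations estimated from these arrays ran from -0.2 (stomatal markers) to 0.63 (photosynthesis), with 1 residual degree of freedom behind each estimate. With the estimated correlations, 0 of the 38 passed. A simulated list with a true shift was missed in the same way, so this setting cannot tell shifted lists from unshifted ones. The p of each called list under the estimated correlation is given beside its count. Medians below are on the log2 scale, mutant over wild type. Counts of called genes stand against 17.2% of all features called (1457 higher and 2382 lower of 22378).

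Glucosinolate synthesis genes rose in 15 of 15 cases, and in 15 of 15 also adjusted over the list alone. The median was 0.94 (adjusted p = 3.16e-25; adjusted p = 0.582 with an estimated correlation). After BCAT4, CYP79F1 and MAM1, the largest rise was that of CYP83A1, a cytochrome P450 that acts on aliphatic aldoximes (3.93-fold, log2 1.97 ± 0.0886). The sulfur deficiency list moved the other way (median -0.82, adjusted p = 1.43e-05; adjusted p = 0.582 with an estimated correlation), with 5 of 8 genes lower and 1 higher, and the same counts adjusted over the list alone. BGLU28, LSU1 (2.29-fold), SDI1 (2.29-fold) and LSU2 (1.79-fold), genes known to be induced by sulfur shortage, fell, while APR1, a reductase of sulfate assimilation, rose 1.52-fold.

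Flavonoid and anthocyanin synthesis fell in 15 of 16 genes, and in 16 of 16 adjusted over the list alone (median -0.53, adjusted p = 6.12e-13; adjusted p = 0.582 with an estimated correlation). TT4, the chalcone synthase that opens the pathway, fell 2.58-fold (log2 -1.37 ± 0.0977), the flavonol synthase FLS1 fell 2.12-fold, TT7 1.85-fold and DFR 1.73-fold. Chlorophyll synthesis fell in 8 of 13 genes, as many adjusted over the list alone (median -0.86, adjusted p = 2.47e-08; adjusted p = 0.582 with an estimated correlation). PORA, a protochlorophyllide reductase, fell 2.80-fold (log2 -1.48 ± 0.0901), HEMA1 and GUN4 2.44-fold each, and CAO, the chlorophyllide a oxygenase, 2.40-fold. The photosynthesis list fell in 15 of 30 genes, 16 adjusted over the list alone (median -0.35, adjusted p = 3.38e-07; adjusted p = 0.690 with an estimated correlation), and 10 of its 11 light-harvesting genes were among those that fell. LHCB2.1 fell 2.52-fold (log2 -1.34 ± 0.119), LHCB3 2.48-fold, LHCB1.1 2.08-fold and LHCA4 1.81-fold (log2 -0.48 in replicate 1 and -1.23 in replicate 2), the last call being lost with robust eBayes (adjusted p = 0.0563; range over alternatives 0.000200 to 1.00), and probes of such near-identical genes may share signal. The size of this shift rested on replicate 2, with a list median of -0.14 in replicate 1 and -0.59 in replicate 2. The 21 of its 30 genes that were brighter than log2 16 had medians of -0.14 and -0.84 on the arrays, and the 9 dimmer ones -0.16 and -0.46. Over the 169 features in that bright range, the medians were 0.10 and -0.29. Genes encoded in the chloroplast fell in 26 of 66 cases and rose in 2, against 40 and 3 adjusted over the list alone (median -0.28, adjusted p = 2.47e-08; adjusted p = 0.690 with an estimated correlation), led by ATCG01130 (1.56-fold). Their median was -0.40 in replicate 1 and -0.14 in replicate 2. Genes encoded in the mitochondrion fell in 9 of 48, 11 adjusted over the list alone (median -0.11, adjusted p = 0.0144; adjusted p = 0.582 with an estimated correlation), led by ATMG00160 (1.44-fold), a call lost with Agilent's log ratios (adjusted p = 0.0539; range over alternatives 2.33e-05 to 1.00). The calls of ATMG00830, ATMG01100 and ATMG00020 were lost with Agilent's log ratios too (adjusted p = 0.132, 0.145 and 0.0730). The mitochondrial shift was lost with median centring (adjusted p = 0.222, range 0.00189 to 0.582).

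The cell cycle list fell in 11 of 17 genes, 12 adjusted over the list alone (median -0.45, adjusted p = 2.47e-08; adjusted p = 0.582 with an estimated correlation). The activator of mitotic proteolysis CDC20.1 fell 1.80-fold, the cytokinesis syntaxin KN 1.73-fold, and the cyclins CYCA1;1 and CYCB1;1 1.60-fold each. Cytokinin response genes fell in 4 of 7 cases (median -0.28, adjusted p = 0.00149, and 0.582 with an estimated correlation), with 6 lower and 1 higher adjusted over the list alone. The response regulators ARR6 and ARR7 fell 2.92-fold and 1.77-fold. The calls of ARR4 and CKX4 were lost without the filter on dim probes (adjusted p = 0.0663 and 0.112). That of ARR4 was also lost with Agilent's log ratios (0.0884), and that of CKX4 with an eBayes trend (0.0902). Expansins and wall loosening genes fell in 6 and rose in 2 of 14 cases, 7 and 2 adjusted over the list alone (median -0.22, adjusted p = 0.0132; adjusted p = 0.582 with an estimated correlation). XTH9 fell 1.65-fold and EXPA8 1.58-fold, and the shift was lost with median centring (adjusted p = 0.157; range over alternatives 0.00225 to 0.582). Cuticular wax genes fell in 7 and rose in 1 of 11 cases, the same counts adjusted over the list alone (median -0.37, adjusted p = 0.000278; adjusted p = 0.582 with an estimated correlation). The wax alkane hydroxylase MAH1 fell 2.60-fold and the regulator MYB96 2.15-fold. Xylem and secondary wall markers rose in 5 and fell in 2 of 10 cases, 7 and 2 adjusted over the list alone (median 0.26, adjusted p = 0.00678; adjusted p = 0.582 with an estimated correlation). FLA12 rose 1.73-fold and the laccase LAC4 1.53-fold, while the xylem peptidase XCP1 fell (log2 -0.38 ± 0.0924). The call of XCP1 was lost with Agilent's log ratios (adjusted p = 0.0588) and without the filter on dim probes (adjusted p = 0.0508; range over alternatives 0.00168 to 1.00). Cytosolic ribosomal protein genes had a median of 0.04, with 7 of 192 higher, 2 adjusted over the list alone (adjusted p = 0.0171, and 0.582 with an estimated correlation). The largest rise was that of AT5G42445 (1.44-fold). The share called higher lay below that over all features (1457 of 22378), and the shift of the list was small. Their median was 0.09 in replicate 1 and 0.03 in replicate 2.

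Phosphate starvation genes fell in 9 of 10 cases, as many adjusted over the list alone (median -0.72, adjusted p = 4.73e-11; adjusted p = 0.582 with an estimated correlation). The galactolipid synthase MGD3 fell 2.69-fold (log2 -1.43 ± 0.105), and the phosphatase PS2 and SRG3 fell 2.33-fold and 2.17-fold. Salicylic acid and defence genes fell in 7 and rose in 1 of 17 cases, the same counts adjusted over the list alone (median -0.16, adjusted p = 0.000921; adjusted p = 0.582 with an estimated correlation). PR5, a pathogenesis-related protein, fell 2.44-fold, LURP1 2.03-fold and ICS1, the isochorismate synthase of salicylic acid synthesis, 1.68-fold. The medians of the single arrays were -0.26 and -0.19. Leaf senescence genes fell in 4 of 18 cases, with 5 lower and 1 higher adjusted over the list alone (median -0.14, adjusted p = 0.0196; adjusted p = 0.589 with an estimated correlation). The senescence regulator NAP fell 3.78-fold (log2 -1.92 ± 0.0894) and the ribonuclease RNS1, well above background in the mutant on 1 of the 2 arrays, was at least 3.17-fold lower (adjusted p = 7.72e-07). The senescence shift was lost when both channels had to be well above background on both arrays (adjusted p = 0.116) and with ranks of limma's statistic (adjusted p = 0.0587; range over alternatives 0.00189 to 0.589). Glutamate, GABA, proline and ammonium genes fell in 4 and rose in 1 of 20 cases, the same counts adjusted over the list alone (median -0.12, adjusted p = 0.0441; adjusted p = 0.802 with an estimated correlation). The asparagine synthetase ASN1 fell 2.26-fold and the proline synthesis gene P5CS1 1.61-fold, and the shift was lost with a normexp offset of 16 (adjusted p = 0.0513), with ranks (adjusted p = 0.0529) and with median centring (adjusted p = 0.133; range over alternatives 0.0112 to 0.802). Its median was -0.17 in replicate 1 and -0.05 in replicate 2.

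The cold acclimation list rose by its median (0.53, against a mean of 0.06, adjusted p = 0.0144, and 0.582 with an estimated correlation). Of its 13 genes, 8 were higher and 3 lower, and 9 and 3 adjusted over the list alone. Its members went both ways, and the grouping by kind given next was not tested. The cold-induced regulators CBF2, CBF3 and CBF1 fell 5.10-fold, 3.19-fold and 3.08-fold (log2 -2.35 ± 0.0882, -1.67 ± 0.0945 and -1.62 ± 0.0908), whereas KIN2, a cold-induced protein often used as a marker of their targets, rose 2.06-fold (log2 1.42 in replicate 1 and 0.66 in replicate 2). In all, 7 of the 8 COR, KIN, RD29A and ERD10 genes rose. The list's shift was lost with median centring (adjusted p = 0.438; range over alternatives 0.000760 to 0.582). The rapid stress and touch response list rose in 5 and fell in 1 of 12 cases, the same counts adjusted over the list alone (median 0.06, adjusted p = 0.0202; adjusted p = 0.582 with an estimated correlation). CML38, a calmodulin-like protein, rose 2.16-fold and WRKY18 1.97-fold, while MYB15 fell 1.79-fold, and the shift was lost with ranks (adjusted p = 0.132), with Agilent's log ratios (adjusted p = 0.121) and against random lists of matched brightness (adjusted p = 0.392; range over alternatives 0.00506 to 0.582). Its medians on the single arrays were 0.15 and 0.08.

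**Figure D3:**
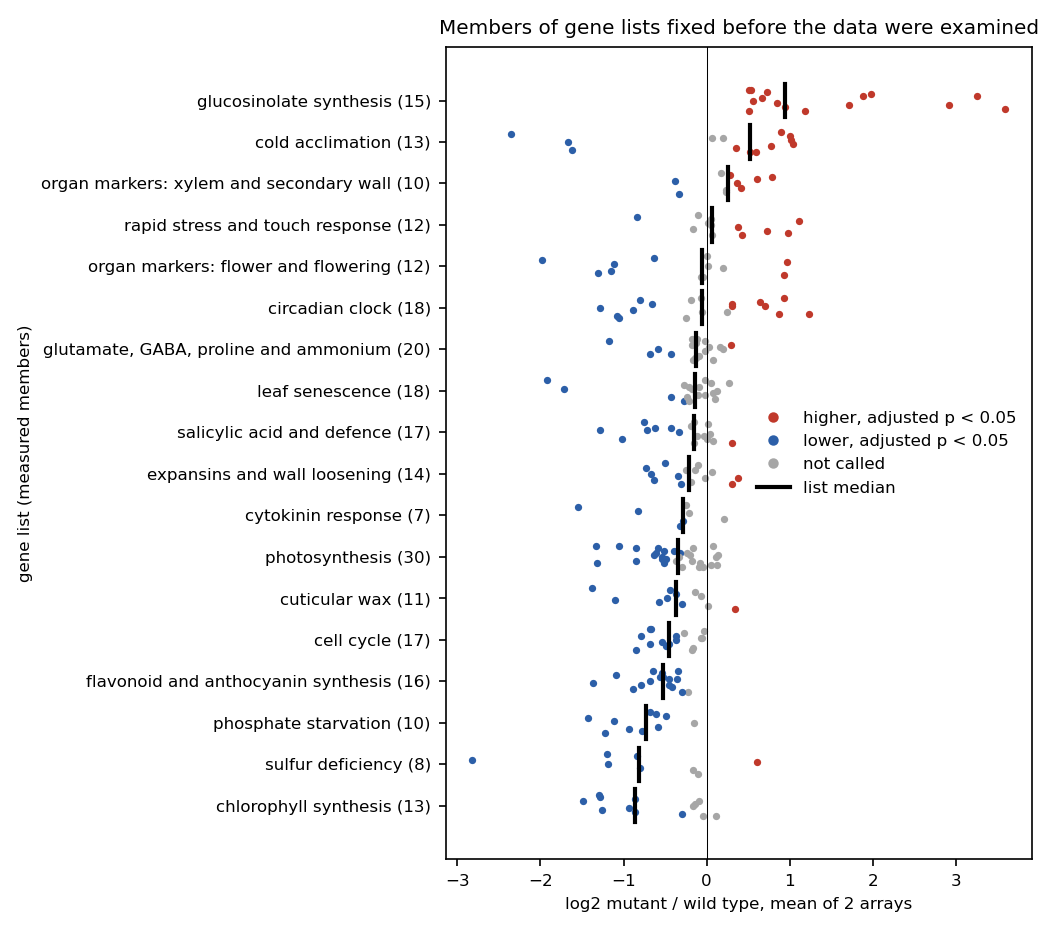
Log2 ratio of mutant over wild type (horizontal, mean of 2 arrays) of each measured member of 16 shifted lists and of the clock and flower lists (vertical, with the number of measured genes), coloured by call, with black bars for list medians. All glucosinolate genes lie above 0, flavonoid and phosphate starvation genes lie below 0, and cold, clock and flower genes lie on both sides.

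The other 19 tested lists did not pass camera with the preset correlation. The circadian clock list had 7 genes higher and 6 lower of 18, 8 and 7 adjusted over the list alone (adjusted p = 0.906), with the morning regulators CCA1, RVE8 and LHY 2.43-fold, 2.11-fold and 2.08-fold lower and the evening gene ELF4 2.34-fold higher. Flower and flowering markers had 5 lower and 2 higher of 12, the same adjusted over the list alone (adjusted p = 0.0568). The petal and stamen identity genes PI and AP3 fell 3.94-fold and 2.48-fold, AP1 and SEP2 fell 2.23-fold and 2.17-fold, and SEP1 rose 1.90-fold. This list passed without background correction (adjusted p = 0.0486), with a normexp offset of 16 (0.0437), with Agilent's log ratios (0.0429), with median centring (0.00189) and without the filter on dim probes (0.0259), and also without the brightest features (0.0445), a setting chosen after the data had been seen. It did not pass with the mean over probes (0.0939), with the stricter filter on dim probes (0.134), with ranks (0.356), against random lists of matched brightness (0.477) or with an estimated correlation (0.582). Aquantile between arrays (0.0570) and eBayes with a trend or robust (0.0568 each) also left it short of the threshold. Among leucine and other aminopeptidases, 2 of 12 genes fell, LAP2 and LAP3, both also adjusted over the list alone (adjusted p = 0.652, median 0.04 and mean -0.40). The list passed with median centring (adjusted p = 0.000312, range over alternatives 0.000312 to 0.849). It holds LAP2 itself (log2 -4.86), so neither that pass nor the mean speaks for the other members.

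Abscisic acid and drought genes were higher in 7 and lower in 8 of 32 cases, 8 and 9 adjusted over the list alone (adjusted p = 0.830). Jasmonate and wounding genes were higher in 7 and lower in 5 of 20, 8 and 5 adjusted over the list alone (adjusted p = 0.743), with CYP94B3, a jasmonate-inactivating oxidase, 2.29-fold lower and JAZ6 1.75-fold higher. Ethylene and jasmonate defence genes were higher in 3 and lower in 4 of 15, 4 and 5 adjusted over the list alone (adjusted p = 0.830). Dark and sugar starvation genes were lower in 3 and higher in 1 of 11, 5 and 2 adjusted over the list alone (adjusted p = 0.0673). They passed against random lists of matched brightness (adjusted p = 0.0112) and without the brightest features (adjusted p = 0.0220; range over alternatives 0.0112 to 0.582), the setting chosen after the data had been seen. Nitrate and ammonium uptake genes were lower in 3 and higher in 1 of 5, as many adjusted over the list alone (adjusted p = 0.111; adjusted p = 0.00760 against random lists of matched brightness, range over alternatives 0.00760 to 0.690), and the nitrate reductase genes NIA1 and NIA2 fell 1.61-fold and 1.51-fold. Oxidative stress genes were lower in 5 and higher in 2 of 19 (adjusted p = 0.419), and endoplasmic reticulum chaperones were higher in 3 and lower in 1 of 10 (adjusted p = 0.0673; adjusted p = 0.0481 with ranks, range over alternatives 0.0481 to 0.693). Auxin response genes were lower in 4 and higher in 2 of 14 (adjusted p = 0.743), branched-chain amino acid and lysine genes higher in 2, IMD1 (3.26-fold) and BCAT3 (1.45-fold), and lower in 2 of 13 (adjusted p = 0.419), and iron deficiency genes higher in 2 and lower in 1 of 7 (adjusted p = 0.419). Those 5 lists had the same counts adjusted over the list alone. The other probe of IMD1 gave a log2 value of 2.83, against 1.70 for the brighter one used.

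Heat shock and hypoxia genes each had 1 higher and 1 lower of 10 (adjusted p = 0.725 and 0.906), and chlorophyll breakdown had 1 higher of 6, NYC1 (1.49-fold; adjusted p = 0.134), with the same counts adjusted over the list alone. Stomatal markers had 2 lower of 5, TMM and SPCH at 1.73-fold and 1.40-fold, with 1 higher added when adjusted over the list alone (adjusted p = 0.382). Proteasome genes had 2 lower of 52, PBB1 and PBB2 (PBB2 at log2 -0.19 in replicate 1 and -0.43 in replicate 2), and 0 adjusted over the list alone (adjusted p = 0.101). That list passed with ranks (adjusted p = 0.0107), against random lists of matched brightness (adjusted p = 0.0181) and without the filter on dim probes (adjusted p = 0.0182; range over alternatives 0.0107 to 0.582). The calls of PBB1 and PBB2 were lost with Agilent's log ratios (adjusted p = 0.0884 and 0.155) and without the filter on dim probes (0.0553 and 0.113), that of PBB2 also with a normexp offset of 16 (0.0526), over ranges of 0.00107 to 1.00 and 0.00522 to 1.00. Autophagy genes had 0 of 14 called in either way (adjusted p = 0.754). Root markers, with 4 measured genes, and seed markers, with 3, were too few to test as lists. Of the root markers, TIP2;3 was 1.53-fold higher (log2 0.05 in replicate 1 and 1.18 in replicate 2) and BGLU23 1.26-fold lower, as when adjusted over the list alone. Both calls were lost with Agilent's log ratios (adjusted p = 0.0590 and 0.0911), without the filter on dim probes (0.150 and 0.0621) and with the mean over probes (0.0564 and 0.0546). That of TIP2;3 was also lost with a normexp offset of 16 (0.0504) and robust eBayes (0.614), and the ranges were 0.000985 to 1.00 and 0.0129 to 1.00. Of the seed markers, EM6 was at least 1.35-fold higher (log2 0.60 in replicate 1 and 0.29 in replicate 2), with the wild type well above background on 1 of the 2 arrays, and 2 were higher adjusted over the list alone. Median, mean and test differed in sign for the aminopeptidase, jasmonate, heat shock and hypoxia lists.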

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

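The arrays carry synthetic spike-in controls (E1A transcripts) that the comparison did not use; this look at them was chosen after the data had been seen. All 10 spike-in probes had a median Cy5 signal above the 99th percentile of the negative controls on both arrays. Their log2 ratios of Cy5 over Cy3 ran from -3.15 to 2.97 in replicate 1 and from -2.93 to 3.01 in replicate 2, and correlated between arrays with r = 1.00. Over genes, the correlation of Cy5 over Cy3 between the same arrays was -0.775. Ratios of the spike-ins thus followed the dye, and those of genes turned with the exchange of genotypes, as the labels state.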

How the results depend on the processing

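Leaving out features brighter than log2 16 was chosen after the data had been seen; the other alternatives were planned. LAP2 stayed below 0 and past the threshold under every tested alternative (log2 -5.37 to -4.70, adjusted p 3.65e-37 to 0.000635; -5.03 and -4.70 on the single arrays), and no named gene or shifted list changed direction. Of 127 further named genes that were called, 85 lost the call with median centring. Outside median centring, 108 kept the call wherever they were tested and 19 lost it in at least 1 alternative. Of these 108, 93 had a value in every alternative for genes. Of the 127, 12 had no value under the stricter filter and 4 none without the brightest features. Among the 19 were also the list members EXPA1, BFN1, GDH1 and ATCG01230 (adjusted p = 0.0569, 0.117, 0.0539 and 0.118 with Agilent's log ratios). With median centring, changed features fell from 3839 to 131 (39 higher, 92 lower), 42 were at least 2-fold higher on both arrays, and r between arrays was -0.00839; without loess, the intensity-dependent dye bias has opposite signs on the turned arrays by construction. Agilent's log ratios gave 2304 changed features (828 higher, 1476 lower), 130 at least 2-fold higher and 380 lower on both arrays, and r = 0.760. Without the dim filter there were 2454 (832 higher), of which 2412 were shared with the main 3839, and r = 0.630; more features were tested, most of them dim. Adding a 2-fold minimum left 290 by construction. The correlation was 0.785 without background correction, 0.767 with an offset of 16, 0.769 with the stricter filter, 0.789 with the mean over probes and 0.782 without the brightest features. Other than as stated, the cause was not tested. On single arrays, 96 to 107 features were at least 2-fold higher and 207 to 222 lower, since only 1 array had to pass; a single array gives no test, so counts of changed features and shifted lists have no value there. No list passed with an estimated correlation (0, against 19), under which a simulated list with a true shift was also missed. Of the 19 shifted lists, 13 kept the call in all 13 other tested alternatives, and 6 lost it in at least 1. Aquantile leaves the ratios within an array as they are and so tests little. No separate paired analysis was made, because both genotypes share each array and the ratio already pairs them. Signal over background, 5.38 to 7.61 per channel, limits dim genes.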

Other observations

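The gene lists in this part, the windows of neighbouring loci, the count of risen floral genes and the setting apart of IMD1 were chosen after the main result had been seen; the tests of further clock and floral genes, of normalization and of probe distances were stated before their outcomes were known, although CAT3, an evening gene, was also on the fixed oxidative stress list. A wider list of the aliphatic branch of glucosinolate synthesis had 21 of 21 genes higher (median 1.97), from MAM3 (log2 0.28, a call lost with Agilent's log ratios and without the dim filter, adjusted p = 0.0665 and 0.111, range over alternatives 0.0296 to 1.00) to BCAT4 (3.59), and held 9 of the 12 highest genes. In the indole branch, 7 of 11 measured genes were higher and 1 lower (median 0.66), with CYP79B2 at 1.19 and the regulator MYB34 at -0.30, a call lost in the same settings (adjusted p = 0.0899 and 0.0861, range 0.00429 to 1.00). The largest rise of any feature was that of a probe without a locus, A_84_P796276, on chromosome 1 from 24086239 to 24086298 (build ath1:Jan2004; 24.1-fold, log2 4.59 ± 0.116, n = 2 arrays, adjusted p = 8.32e-12).

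Morning clock genes were lower and evening clock genes higher in the mutant. In the fixed clock list, 6 of 8 morning genes fell (mean -0.77) and 7 of 9 evening genes rose (mean 0.57). The difference between evening and morning means was 1.35, and it stayed at or above 1.37 under 4 other background corrections and normalizations. A dye bias shared by both arrays cancels in the mean over exchanged dyes, whatever the normalization. The test therefore says little about normalization. In genes outside the clock list, 9 of 10 morning genes fell while RVE2 rose, and 3 of 8 evening genes rose while 2 fell. The evening mean lay 0.913 above the morning mean (exact permutation test over genes, two-sided, p = 0.00560, or 0.966 with p = 0.00581 without CAT3). That p measures the spread between genes, which need not be independent of one another, and not the spread between arrays or plants. The difference has the direction predicted for a different time of day at harvest or a shifted clock phase. These 2 readings cannot be separated here, as the time of harvest is not given in the sources used here. An effect of the genotype on the clock stays open and untested. Whether either reading contributed to the other changes described above was not tested.

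GRP16, GRP17, GRP19, PI and AP3, genes with known roles in the pollen coat or in stamen identity, were lower in the mutant. A lower amount of every floral transcript is argued against only in that 1 of 7 floral homeotic genes, SEP1, rose while 5 fell, a count known before that test was written. Less flower bud tissue in the mutant samples stays open, as neither predicted outcome was met. The 8 measured carpel and ovule genes had a median of -0.202, with 2 lower. The 10 further anther and pollen genes had a median of -0.0715, with 4 lower and 2 higher. VGD1, GRP20, GRP18 and AGP6 were lower (log2 -1.42, -1.33, -0.49 and -0.41), and ACOS5 and LAP5 were higher (0.34 and 0.45). The others were not called. LAP5 here is AT4G34850, which is not among the aminopeptidases named above. GRP18 (AT5G07520) and GRP20 (AT5G07560) adjoin GRP16, GRP17 and GRP19, so they do not stand apart from the genes that raised the pattern. The organ sampled is not given in the sources used here, and a developmental difference between the genotypes was not tested.

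Aliphatic glucosinolate genes were higher in the mutant, AOP2 among them. A segment of another accession around AOP2 stays open, since a short one would give the same count: AOP2 was the only gene (1) at least 2-fold different on both arrays among the 50 tested loci centred on it, within the 95th percentile of windows in random orders (2). A long chromosome segment of another accession in the mutant, elsewhere, stays open as well: the most crowded window of 50 loci held 7 such genes, above the 99th percentile of the most crowded window in 1000 random orders (6), among them MYB29, a regulator on the aliphatic list that rose (log2 1.88), PMSR2 and GDPD6, but the other 4 were the neighbouring GRP16, GRP17, GRP19 and GRP20, which random orders scatter, and with these counted once that window held 4 and the most crowded window of all 6. A sequence difference under single probes stays open too: over the 5 genes with several probes the planned test met what it predicts, since the 2 probes of IMD1 both rose but lay 1.13 (log2) apart, while those of CYP79F1, AOP2, BAT5 and MAM1 lay within 0.565 of one another and 16 genes have a single probe. A change in regulation of the pathway in the mutant is a candidate explanation that was not tested.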
